A study of Homo sapiens with 12 samples.

How the data were processed

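RNA was sequenced from MDA-MB-231 cells, a human triple-negative breast cancer line that lacks oestrogen and progesterone receptors and HER2 amplification. The cells expressed either the wild-type glucocorticoid receptor (WT-GR) or a receptor whose phosphorylated serine was replaced by alanine (S134A-GR). Per the labels' protocols, cells were starved for 18 h in medium with 1% DCC and then given vehicle or 1 µM dexamethasone (Dex), a synthetic agonist of the glucocorticoid receptor, for 6 h. Poly(A) libraries were made with a TruSeq kit and read as 75-base pairs on an Illumina HiSeq instrument. There were 12 libraries, 3 in each of the 4 groups of genotype by treatment. The labels do not say whether the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

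Per the submitters' processing notes, FastQC 0.11.7, featureCounts of the Subread package, DESeq2 1.22.2 and the hg38 build were used, and no role or order is given for them. The aligner and the gene annotation are not given in the sources used here. Each deposited file holds 1 normalized signal value per gene, a read count divided by a size factor of its library, for 19907 genes. This unit was read from the values themselves: within each library every value was a whole multiple of the smallest step, within a tolerance of 0.01 reads, so that 100% of values gave whole reads. The recovered totals ran from 56.4 to 100.6 M reads (M, mega) and averaged 85.2 M, above the mean the labels state. Even counts were over-represented among genes with few reads (58.2 to 67.5% of counts from 1 to 20), a pattern that counting both mates of a read pair gives. The number of independent fragments is then smaller than the recovered totals, and any precision taken from counting alone is overstated, while tests that use the spread between libraries do not rest on it. No gene name was blank, and no mitochondrially encoded gene was analysed here.

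The gene names of the Dex files had to be repaired before any comparison. Each Dex file lists 26485 names but only its first 19907 lines hold a value, which leaves 6578 names without one. The vehicle names are an ordered subset of the Dex names, and the lists part from line 9 on, so that only 8 lines carry the same name in both kinds of file. In the Dex files, 28 names had also been turned into dates. Matched by line, the log2 values of the 6 Dex libraries correlated with the vehicle mean at r = 0.9816 to 0.9886 across genes, and matched by the 14926 shared names at r = -0.0056 to -0.0036. In every Dex library all 99 windows of 200 lines matched the vehicle values best at the same line, among shifts of up to 5 lines. The Dex values were therefore given the names of the vehicle files by line order. Every Dex result rests on this repair, and results with the names as deposited are among the alternatives.

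The main test was limma 3.58.1 with a mean-variance trend on log2(value + 1), in R 4.3.3. Genes with a value of at least 10 in at least 3 libraries were tested (15957 genes), p-values were two-sided, and the Benjamini-Hochberg adjusted threshold was 0.05. A fold change on this scale understates the change of genes with low values. All 12 libraries entered 1 fit with 1 coefficient per group, so that the groups share the estimate of the spread. The 5 comparisons were Dex against vehicle in each genotype, the difference between these responses, and S134A-GR against WT-GR cells in vehicle and in Dex. Before the data were examined, edgeR's quasi-likelihood test on raw counts had been fixed as the main test. Because the files hold normalized values, limma took its place, and edgeR 4.0.16 and DESeq2 1.42.0 were run on the recovered reads as alternatives. Scaling by library size only was also an edgeR fit on recovered reads, so beside limma both test and scaling differ, and beside edgeR with TMM the scaling alone. edgeR with TMM called 4440 genes for Dex in WT-GR cells, 2528 in S134A-GR cells, 61 for the difference of responses, 8021 for genotype in vehicle and 7855 in Dex.

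Fixed at the same time as the tests were 27 gene lists (574 distinct symbols, of which 19 were found under an older symbol and 37 were not found), and 26 of them could be tested. They cover glucocorticoid-induced genes, the pyruvate dehydrogenase complex, glycolysis, the TCA cycle, the respiratory chain, fatty acid oxidation, epithelial-mesenchymal transition, migration and adhesion, NF-kB targets, immediate-early genes, TGF-beta targets, the p38 pathway, the circadian clock, interferon, hypoxia, cholesterol, ATF4 and the unfolded protein response, DNA replication, mitosis, growth arrest and apoptosis, nuclear receptor cofactors, luminal and basal breast markers, blood cell markers, histones and housekeeping genes. Lists were tested with camera of limma, which compares a list with all other genes, at a preset inter-gene correlation of 0.01, and also with an estimated correlation and with fry, with adjustment over the lists of a comparison. Camera had been fixed for voom values, log2 counts weighted by their precision, and was run on log2(value + 1) instead. Genes named in the text were chosen by a fixed rule. It took the 10 largest fitted changes per direction for Dex in WT-GR cells, for the difference of responses and for genotype in vehicle, and 5 per direction in the other comparisons. These genes needed an adjusted p under 0.05, a mean of at least 1 CPM, group values that did not overlap, and an ordinary gene symbol. NR3C1, PDK4 and up to 4 members of each list with the smallest p were added. Some genes that the rule names are not reported here.

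limma was tested on simulated reads drawn from the WT-GR vehicle means and the library size factors, so without any genotype difference. Each gene had 1 dispersion in all groups. At each size of change 50 genes were changed, none of them with low values. The real groups differed in spread and in many more genes, so the simulated percentages do not carry over to them directly. For Dex in WT-GR cells it recovered 36% of genes changed by 1.25-fold, 86% by 1.5-fold, 92% by 2-fold and 100% by 4-fold among 15606 genes, and 8.2% of its calls were unchanged genes. For the difference of responses it recovered 8%, 48%, 82% and 92% at these sizes among 15593 genes, and 2.5% of its calls were unchanged genes. No pair of replicates was a duplicate: the chi-square statistic over its degrees of freedom was 7.65 to 46.21 for each pair within a group. The alternatives tried were other normalizations, tools, filters and pseudocounts, a fit of the compared groups alone, the replicate number as a block, a fold threshold, library weights, the deposited names, and leaving out each library.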

Results

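The data are gene-level mRNA levels in MDA-MB-231 breast cancer cells with WT-GR or S134A-GR, each after 6 h of vehicle or 1 µM Dex, with 3 libraries per group. Values are normalized read counts, given as mean ± SD with n = 3 in every group. Recovered depth was 56.4, 85.8 and 86.2 M reads in WT-GR vehicle, 56.9, 93.8 and 93 M in WT-GR Dex, 91.6, 85.2 and 96.8 M in S134A-GR vehicle, and 82.4, 100.6 and 93.6 M in S134A-GR Dex. The first principal component, with 52.5% of the variance, separated the genotypes and the second, with 15.7%, separated Dex from vehicle. The WT-GR Dex libraries varied most, with a median SD of 0.148 on the log2 scale against 0.094, 0.065 and 0.091 in WT-GR vehicle, S134A-GR vehicle and S134A-GR Dex. WT-GR Dex replicates 2 and 3 held 193 and 210 genes with exactly 1 read, against 352 to 409 in the other 10 libraries. All Dex values carry gene names repaired by line order.

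The series asks how Dex acts in cells whose receptor lacks the phosphorylation site, and names PDK4, a kinase that inhibits pyruvate dehydrogenase and so limits entry of pyruvate into the TCA cycle. PDK4 (chromosome 7, 95583499 to 95596491, GRCh38) rose with Dex from 763 ± 45.1 to 3705 ± 239 in WT-GR cells, 4.86-fold, and from 492 ± 44.9 to 2232 ± 83.1 in S134A-GR cells, 4.54-fold. The log2 changes were 2.28 and 2.18, with limma adjusted p = 1.64e-10 and 2.06e-10. Their difference was -0.09 ± 0.11 (SE), with limma adjusted p = 0.683, so that no difference between the PDK4 responses was detected. PDK4 was lower in S134A-GR cells in both treatments, by a log2 difference of -0.64 in vehicle and -0.73 in Dex (limma adjusted p = 2.06e-05 and 6.29e-06). The 3 S134A-GR values lay below the 3 WT-GR values in each treatment.

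NR3C1, the gene of the glucocorticoid receptor itself (chromosome 5, 143277931 to 143435512, GRCh38), was counted at 12730, 12140 and 10440 in WT-GR vehicle, 9214, 8707 and 10250 in WT-GR Dex, 8516, 8971 and 8959 in S134A-GR vehicle, and 8354, 7529 and 7469 in S134A-GR Dex. A gene count cannot show a point mutation, so these values do not check the genotype labels. With Dex, NR3C1 fell in WT-GR cells (log2 change -0.32, limma adjusted p = 0.00673), and its change in S134A-GR cells was -0.18 (limma adjusted p = 0.145). The difference between these responses was 0.14 (limma adjusted p = 0.497). NR3C1 was lower in S134A-GR than in WT-GR cells, by -0.41 in vehicle and -0.27 in Dex (limma adjusted p = 0.000518 and 0.0099). The call in Dex was lost with scaling by library size only, at -0.15, and without WT-GR Dex replicates 2 and 3, at -0.25.

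**Figure D1:**
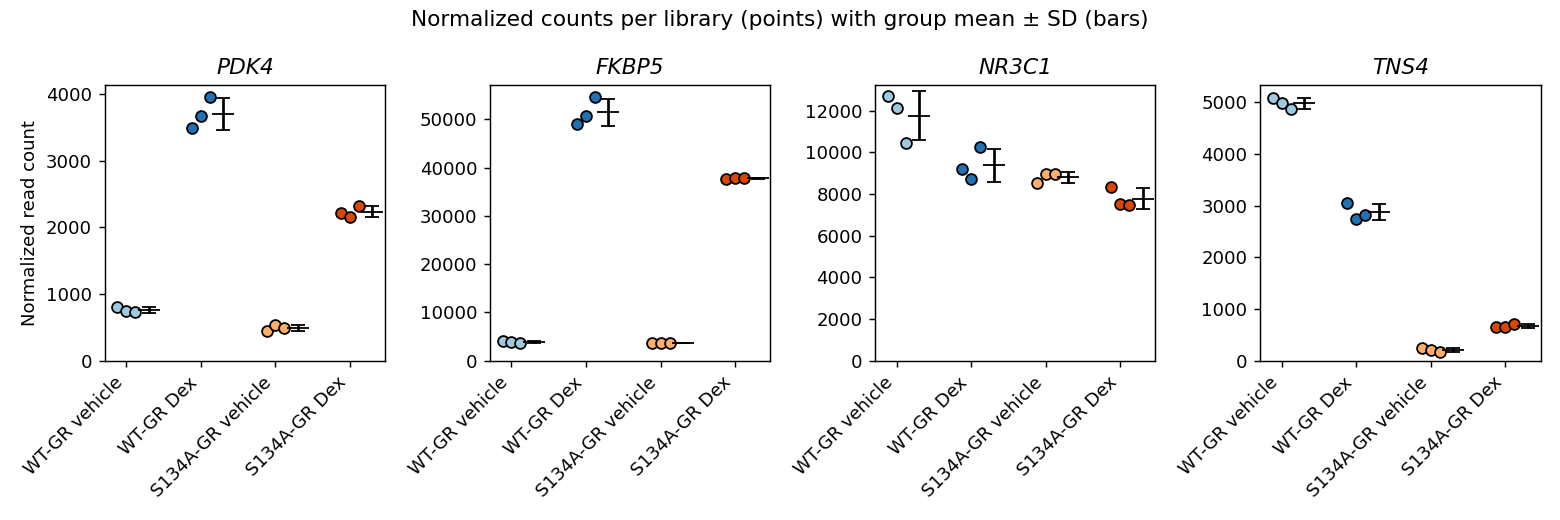
Normalized read counts of PDK4, FKBP5, NR3C1 and TNS4 in each of the 12 libraries (points), with group mean ± SD (bars, n = 3), on linear axes that start at 0. PDK4 and FKBP5 are higher with Dex in both genotypes, while TNS4 is lower with Dex in WT-GR and higher in S134A-GR cells.

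In WT-GR cells Dex raised classical targets of the receptor. TSC22D3, the anti-inflammatory leucine zipper protein GILZ, rose 20.7-fold, from 3010 ± 132 to 62230 ± 1070, FKBP5, a co-chaperone that restrains the receptor, rose 13.1-fold to 51430 ± 2838, and the transcription factor KLF9 rose 17-fold to 2238 ± 148. IP6K3 was at 0 in every WT-GR vehicle library and at 276 ± 22.1 with Dex. The lipid droplet gene CIDEC went from 3.71 ± 3.18 to 578 ± 137 and the dipeptidase DPEP1 from 3.58 ± 3.31 to 488 ± 27.4. LDB3, CPNE7, the VEGF receptor KDR and the acute-phase gene SAA1 rose by 4.01, 3.85, 3.67 and 3.26 on the log2 scale.

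Secreted inflammatory and invasive factors were among the genes that fell in WT-GR cells. The cytokines IL11 and IL1B had log2 changes of -2.34 and -2.22, and PLAU, the urokinase plasminogen activator, fell from 67740 ± 2921 to 17950 ± 423. The R-spondin receptor LGR5 fell by 2.91, the epithelial transcription factor ELF3 by 2.57, the death ligand TNFSF10 by 2.52, PLEKHG4B by 2.42 and the survival gene BCL2A1 by 1.86. The rule also named RPS9, with a log2 change of -2.96, but it is uncertain, since its counts varied widely within groups (377 ± 495 in S134A-GR vehicle). In total limma called 4455 of 15957 genes at an adjusted p under 0.05, 2216 higher and 2239 lower, of which 583 changed at least 2-fold. Values did not overlap between the groups for 35.1% of genes, where chance gives 10%. The share of calls that were higher was 49.7%, and in edgeR it was 55.2% with TMM and 32.4% with scaling by library size only. The count was 2963 without WT-GR vehicle replicate 2, 2490 with the other genotype left out of the fit and 7113 with library weights.

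Of the 27 glucocorticoid-induced genes measured, 24 rose in WT-GR cells (25 adjusted over the list alone), with a median log2 change of 1.98. They included DUSP1, a phosphatase that shuts off MAP kinases (3.18), the clock gene PER1 (2.95), the lipoprotein lipase inhibitor ANGPTL4 (2.78) and BIRC3 (1.79). The camera test of limma gave adjusted p = 9.66e-35 (adjusted p = 0.00016 with an estimated correlation). Among 23 type I interferon genes 14 fell and 1 rose (16 and 3 adjusted over the list alone), with OASL at -0.55, IFI44L at -0.93 and the RNA sensor DDX58 at -0.7. The limma camera adjusted p was 0.000372 (adjusted p = 0.0254 with an estimated correlation). These were the lists that kept their calls with an estimated correlation.

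The other lists past the threshold in WT-GR cells lost it with an estimated correlation. Among 22 DNA replication genes 15 fell (18 adjusted over the list alone), with cyclin E2 (CCNE2) at -1.07, CDC6 at -0.57 and E2F1 at -0.5. Their limma camera adjusted p was 4.09e-06 (adjusted p = 0.0539 with an estimated correlation). Of 21 growth arrest and apoptosis genes 10 rose and 3 fell (11 and 4 adjusted over the list alone). The survival genes MCL1 and BCL2L1 rose by 0.83 and 0.84 and TXNIP, an inhibitor of glucose uptake, by 1.31, so that the risen members included inhibitors of apoptosis. The limma camera adjusted p was 0.00343 (adjusted p = 0.206 with an estimated correlation). Of 34 respiratory chain subunits 10 rose (12 adjusted over the list alone), including NDUFA2 at 0.33 and COX5B at 0.34, but in edgeR 12 rose with TMM and 3 with scaling by library size only. The limma camera adjusted p was 0.00424 (adjusted p = 0.686 with an estimated correlation). Of 25 NF-kB and cytokine genes 10 fell and 5 rose (13 and 6 adjusted over the list alone), and the limma camera adjusted p was 0.0448 (adjusted p = 0.564 with an estimated correlation).

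S134A-GR cells answered Dex with many of the same targets. TSC22D3 rose 19.7-fold to 40550 ± 258, FKBP5 10.1-fold to 37840 ± 120, and DUSP1 7.53-fold to 24170 ± 723. IP6K3 went from 2.48 ± 2.89 to 273 ± 39.3, CIDEC from 3.83 ± 1.95 to 513 ± 71.9, DPEP1 from 14.8 ± 6.62 to 1069 ± 84.5, and EDN2, which encodes the vasoconstrictor endothelin, from 39.2 ± 8.04 to 943 ± 31. IL11 fell by 2.57, the p38 kinase activator MAP2K6 by 2.51, and IL1B by 2.18 on the log2 scale, and PLAU and LONRF2 had log2 changes of -2.17 and -2.17. GTPBP6 also met the rule, at 5.47, but its counts were erratic within groups and it has a copy on each sex chromosome, so it is uncertain. limma called 2513 genes at an adjusted p under 0.05, 1275 higher and 1238 lower, of which 413 changed at least 2-fold, and 5116 with library weights. With the other genotype left out of the fit the count was 3439, above the 2490 of WT-GR cells in such a fit. Which genotype had more calls thus depended on whether the groups shared the estimate of the spread. Values did not overlap for 38.6% of genes, where chance gives 10%.

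Glucocorticoid-induced genes rose in 23 of 27 cases in S134A-GR cells (23 adjusted over the list alone), with a median log2 change of 1.62 and limma camera adjusted p = 1.91e-43 (adjusted p = 6.8e-05 with an estimated correlation). Interferon genes fell in 9 of 23 cases (14 adjusted over the list alone), with OASL at -0.94 and DDX58 at -0.65 and limma camera adjusted p = 1.44e-05 (adjusted p = 0.00955 with an estimated correlation). DNA replication genes fell in 9 of 22 cases (12 adjusted over the list alone), with CDC6 at -0.43 and E2F1 at -0.33 and limma camera adjusted p = 2.6e-06 (adjusted p = 0.0493 with an estimated correlation). These 3 lists held with an estimated correlation.

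Several metabolic and signalling lists also passed in S134A-GR cells but lost the call with an estimated correlation. Of 23 glycolysis genes 8 fell and 1 rose (8 and 2 adjusted over the list alone). The glucose transporter SLC2A1 and the hexokinase HK2 fell by 0.53 and 0.54, and the bifunctional enzymes PFKFB3 and PFKFB4, which set the level of a glycolytic activator, by 0.59 and 0.53. The limma camera adjusted p was 0.001 (adjusted p = 0.341 with an estimated correlation). Of 26 immediate-early genes 11 fell and 4 rose (13 and 4 adjusted over the list alone), with JUN at -1.5 and the growth factor HBEGF at -1.28, and limma camera adjusted p = 0.001 (adjusted p = 0.293 with an estimated correlation). Cholesterol genes fell in 5 of 20 cases (5 adjusted over the list alone), with INSIG1 at -0.51 and HMGCS1 at -0.39, and limma camera adjusted p = 0.0074 (adjusted p = 0.341 with an estimated correlation). Of 26 p38 pathway genes 7 rose and 3 fell (10 and 3 adjusted over the list alone), with the stress sensor GADD45A at 1.21, and limma camera adjusted p = 0.00793 (adjusted p = 0.0663 with an estimated correlation). Of 21 growth arrest and apoptosis genes 9 rose and 5 fell (9 and 7 adjusted over the list alone), with MCL1 at 0.79, and limma camera adjusted p = 0.00793 (adjusted p = 0.264 with an estimated correlation). Of 20 hypoxia genes 12 fell and 3 rose (13 and 3 adjusted over the list alone), with the angiogenic factor VEGFA at -1.05. Their median was -0.23 and their mean 0.03, which differ in sign, and the limma camera test was downward at adjusted p = 0.0159 (adjusted p = 0.341 with an estimated correlation). Of 25 NF-kB genes 9 fell and 4 rose (11 and 5 adjusted over the list alone), with limma camera adjusted p = 0.0184 (adjusted p = 0.341 with an estimated correlation).

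Members of these lists also changed in WT-GR cells, where 5 of the lists did not pass. There 6 glycolysis genes fell and 4 rose (limma camera adjusted p = 0.553), 9 immediate-early genes fell and 5 rose (adjusted p = 0.153), and 7 cholesterol genes fell and 1 rose (adjusted p = 0.204). Of p38 pathway genes 7 rose and 4 fell (limma camera adjusted p = 0.153), and of hypoxia genes 9 fell and 4 rose (adjusted p = 0.153, with a median of -0.19, a mean of 0.01 and a downward test). Adjusted over the list alone, 7 cholesterol genes fell and 2 rose, 8 p38 genes rose and 4 fell, 11 hypoxia genes fell and 4 rose, and the other 2 lists kept their counts. By limma's camera on the difference of responses glycolysis passed (adjusted p = 0.015, and adjusted p = 0.861 with an estimated correlation), while immediate-early (0.0658), cholesterol (0.652), p38 (0.926) and hypoxia genes (0.984) did not, so no difference between the genotypes was shown for these 4. Of 34 respiratory chain subunits limma called 0 in S134A-GR cells, with 1 at an unadjusted p under 0.05, 0 by edgeR and 1 by DESeq2 (limma camera adjusted p = 0.882).

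The responses of both genotypes overlapped. By limma's test of the difference itself 66 of 15957 genes passed the adjusted threshold, while 2790 had an unadjusted p under 0.05. The short list of calls does not show that few genes differed, since the test recovered few of the smallest simulated differences. Of the genes called by limma for Dex in both genotypes, 924 rose in both, where independent lists would share 177.1. Another 848 fell in both, where they would share 173.7, and 8 moved in opposite directions. The last count was 42 without WT-GR Dex replicate 3, and 5 without WT-GR vehicle replicate 2, S134A-GR vehicle replicate 1 or 3 or S134A-GR Dex replicate 1. These comparisons share no library, but they share each gene's estimate of the spread, so their calls are not independent. With only the compared groups fitted, which shares no such estimate, 822 rose and 724 fell in both. Independent lists would then share 132 and 136.3. Over the 4712 genes called for the mean Dex effect of both genotypes, the median signed log2 response was 0.323 in WT-GR and 0.258 in S134A-GR cells. The ratio of these medians was 0.80, with a jackknife SE of 0.242 over libraries, so that it did not stand apart from 1. That does not show responses of equal size, and the SE is rough, since it ignores the groups. The ratio was 0.59 without WT-GR Dex replicate 3, 0.60 with library weights and 0.48 without WT-GR Dex replicates 2 and 3. Its highest value with the repaired names was 0.85, without WT-GR Dex replicate 1.

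TNS4, a focal adhesion adaptor, went in opposite directions. It fell from 4976 ± 109 to 2871 ± 157 with Dex in WT-GR cells and rose from 200 ± 38.2 to 671 ± 34.4 in S134A-GR cells, a difference in log2 response of 2.55 (limma adjusted p = 4.53e-06). Rises larger on the log2 scale in S134A-GR cells were seen for EDN2 (difference 1.63), the alkaline phosphatase gene ALPP (1.41), the caveolar gene SDPR (1.14), STON2 (1.02), FGD4 (0.9) and the matrix cross-linking enzyme LOX (0.69). EDN2, ALPP and SDPR started lower there in vehicle, by log2 differences of -2.16, -2.51 and -1.66, and gained more counts in WT-GR cells, as ALPP did from 655 ± 67.6 to 3909 ± 262 against 115 ± 24.6 to 1816 ± 174. SLC2A14, a glucose transporter gene nearly identical to SLC2A3 and so uncertain, differed by 1.47. FAM65C, GPR89A and CCDC138 fell in WT-GR cells, and their responses differed by 2.07, 0.94 and 0.9. FAM65C was already much lower in S134A-GR vehicle (log2 difference -4.84), at 23.56, 14.19 and 14.25 against 488.8, 481.9 and 566.5 in WT-GR vehicle. Its S134A-GR response was thus measured at low values and left little room for a fall. Rises smaller on the log2 scale in S134A-GR cells were seen for the sarcomere gene LDB3 (difference -1.44), the transcription factor ATOH8 (-1.02), the membrane protein gene STOM (-1.01), GATSL3 (-0.96), glutamine synthetase (GLUL, -0.51) and FKBP5 (-0.38). The sphingosine phosphate receptor S1PR3 (-1.18), the interleukin 6 receptor IL6R (-0.89) and the atrophy-associated ubiquitin ligase FBXO32 (-0.78) rose in WT-GR cells, and FBXO32 fell in S134A-GR cells (0.54 against -0.24), a call lost without S134A-GR vehicle replicate 1 (-0.2). NRG2 fell in both genotypes (-0.43 against -1.46, difference -1.03), in WT-GR cells not past the threshold without WT-GR Dex replicates 2 and 3 (-0.33), and INPP5J (-0.92) fell in S134A-GR cells. GTF2IRD2B, which has a near-identical paralog, rose in WT-GR and fell in S134A-GR cells (difference -1.65) and is uncertain, its fall being lost without S134A-GR vehicle replicate 3 (-0.58) or Dex replicate 1 (-0.61).

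limma called 66 genes for the difference of responses, 38 with a higher and 28 with a lower value in S134A-GR cells, and 13 differed at least 2-fold. The 13 became 75 without WT-GR Dex replicate 3, 21 without WT-GR Dex replicate 1, 6 without WT-GR vehicle replicate 2, and 8 without S134A-GR vehicle replicate 3 or Dex replicate 1. Of the 66, 21 had fitted responses of opposite sign, 36 a larger and 30 a smaller absolute response in S134A-GR cells, and 43 were also called for genotype in vehicle. The count of 66 depended on single libraries. It was 1604 without WT-GR Dex replicate 3, and 26 to 37 without WT-GR vehicle replicate 1 or 2 or any 1 of the 6 S134A-GR libraries. It was 504 with DESeq2, 2854 with library weights and 2550 without WT-GR Dex replicates 2 and 3. CCDC138, STON2, FGD4, ATOH8, GPR89A, LDB3, S1PR3, FKBP5, INPP5J, SLC2A14, IL6R and NRG2 lost their call in 6 to 14 of 23 alternatives and FAM65C in 2. Respiratory chain and glycolysis genes had lower responses in S134A-GR cells by the limma camera test (adjusted p = 0.00435 and 0.015), and neither call held (adjusted p = 0.861 for both with an estimated correlation). Of their single members limma called 0, while 9 of 34 and 7 of 23 had an unadjusted p under 0.05. Over the list alone 1 and 4 were called, edgeR called 0 and 0, and DESeq2 called 1 and 2.

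**Figure D2:**
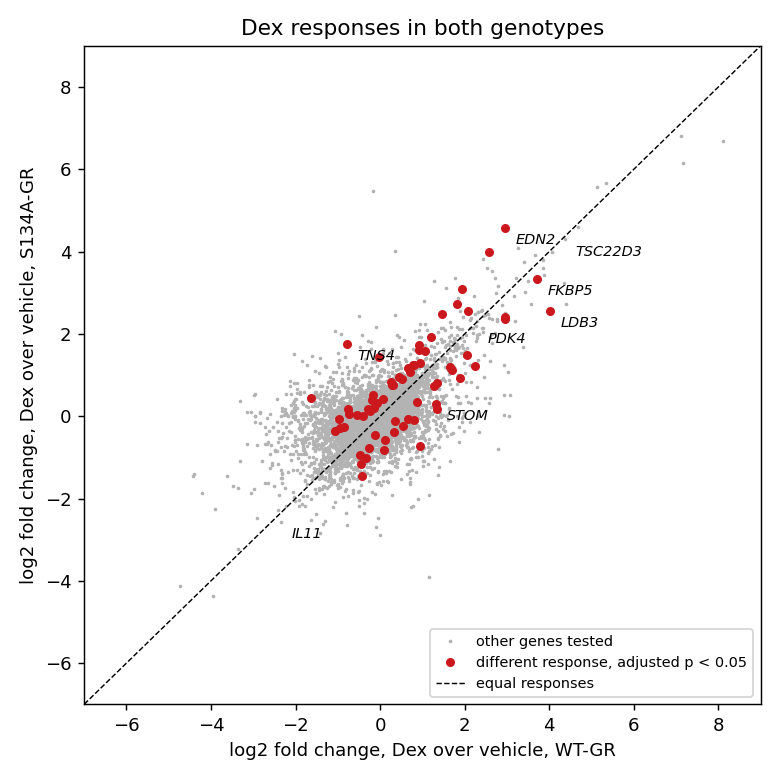
Log2 fold change with Dex in WT-GR cells (horizontal) against S134A-GR cells (vertical) for each of 15957 genes. Red points are the 66 genes with a different response, and the dashed line marks equal responses.

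The genotypes differed far more than the treatments, already in vehicle. NUP210, a nuclear pore component, was at 2234 ± 139 in WT-GR and 12.7 ± 7.38 in S134A-GR cells, the lineage transcription factor NKX2-1 at 422 ± 53.5 and 2.26 ± 1.61, and HCLS1, a cortactin relative of blood cells, at 1666 ± 48.5 and 9.7 ± 5.75. The mucosal secretory genes AGR2, TFF3 and MUC5AC were at 1174 ± 35.6, 577 ± 100 and 446 ± 318 in WT-GR cells and at 7.4 ± 7.54, 0.594 ± 1.03 and 1.65 ± 2.13 in S134A-GR cells. SLITRK1, PNPLA4 and ASRGL1 were at 0 in every S134A-GR vehicle library and at 650 ± 69.4, 238 ± 35.1 and 192 ± 18.2 in WT-GR cells, and GRAMD1B was at 0.628 ± 1.09 against 357 ± 30.3. In the other direction DMD, the dystrophin gene, was at 2356 ± 47.9 in S134A-GR and 54.9 ± 12.6 in WT-GR cells, ZNF300 at 426 ± 11 and 2.84 ± 2.66, and the secreted matrix protein SPP1 at 1611 ± 71 and 98.2 ± 21.3. LYPLAL1-AS1, THSD7B, GPR78, IGFN1, the laminin receptor subunit ITGA7 and SPANXB1 were higher by 3.77, 3.74, 3.35, 3.12, 2.82 and 2.64 on the log2 scale. LYPLAL1-AS1 is an antisense gene and is uncertain, since no strand setting is stated. RPS18 met the rule at 5.52, but its values varied widely within groups (10760 ± 17780 in S134A-GR Dex) and it is uncertain.

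limma called 8061 genes for genotype in vehicle, 3804 higher and 4257 lower in S134A-GR cells, of which 1355 differed at least 2-fold. Values did not overlap for 64.3% of genes, where chance gives 10%. The share of higher calls was 47.2%, and in edgeR it was 49% with TMM and 59.6% with scaling by library size only. The labels name no separate lines within a genotype and do not say whether each is a clone or a pool. The mutation therefore cannot be separated from any other difference between the lines.

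The list tests in vehicle that passed were all downward in S134A-GR cells. With an estimated correlation limma's camera called 0 of 26 lists, with 4 at an unadjusted p under 0.05, while fry called 22. Cholesterol genes were lower in 16 of 20 cases (16 adjusted over the list alone), with INSIG1 at -0.94, a median of -0.52 and limma camera adjusted p = 2.67e-06 (adjusted p = 0.125 with an estimated correlation). With scaling by library size only 15 were lower and 2 higher. ATF4 and unfolded protein response genes were lower in 18 of 24 cases (18 adjusted over the list alone), with asparagine synthetase (ASNS) at -1.18 and XBP1 at -0.77, and limma camera adjusted p = 6.82e-06 (adjusted p = 0.0821 with an estimated correlation). Of 20 hypoxia genes 14 were lower and 3 higher (14 and 3 adjusted over the list alone), with CA9 at -0.88 and VEGFA at -0.98, and limma camera adjusted p = 0.000798 (adjusted p = 0.225 with an estimated correlation). Of 15 luminal epithelial markers 10 were lower and 1 higher (10 and 1 adjusted over the list alone), with the keratin KRT19 at -2.31 and SPDEF at -2.21, a median of -1.44 and limma camera adjusted p = 0.00199 (adjusted p = 0.125 with an estimated correlation). Of 23 glycolysis genes 14 were lower and 3 higher (15 and 3 adjusted over the list alone), with LDHA at -0.54 and ENO1 at -0.47, and limma camera adjusted p = 0.0259 (adjusted p = 0.517 with an estimated correlation). Of 23 interferon genes 13 were lower and 5 higher (13 and 5 adjusted over the list alone), with BST2 at -3.98 and IFIT2 at -1.22, and limma camera adjusted p = 0.0259 (adjusted p = 0.125 with an estimated correlation). Of 25 NF-kB genes 14 were lower and 5 higher (14 and 5 adjusted over the list alone), with the adhesion receptor ICAM1 at -3.83 and the collagenase MMP1 at -1.71, and limma camera adjusted p = 0.0371 (adjusted p = 0.496 with an estimated correlation).

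**Figure D3:**
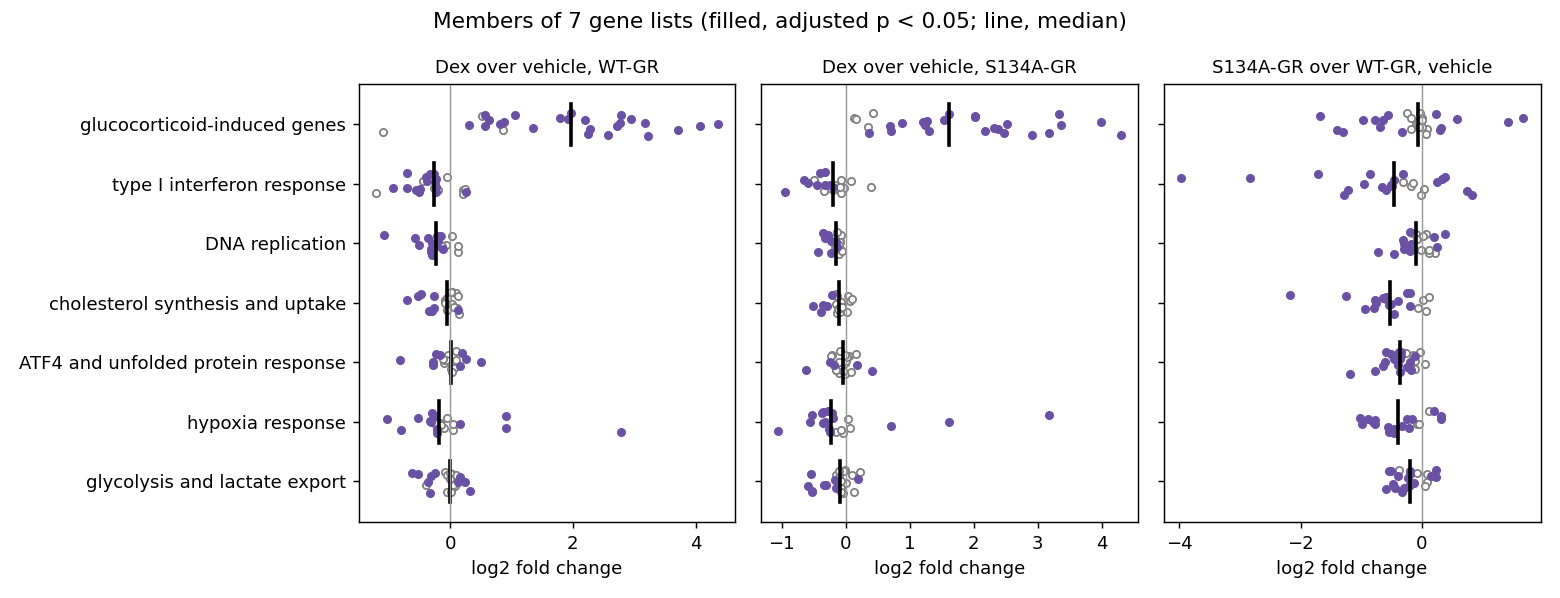
Log2 fold change of each measured member of 7 gene lists for Dex in WT-GR cells, Dex in S134A-GR cells, and S134A-GR over WT-GR cells in vehicle (filled points, adjusted p under 0.05; lines, medians). Glucocorticoid-induced genes have medians of 1.98 and 1.62 in the Dex comparisons, and cholesterol genes a median of -0.52 in the genotype comparison.

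With Dex present, the genotypes differed in much the same genes. AGR2 was at 905 ± 150 in WT-GR and 0.352 ± 0.61 in S134A-GR cells, TFF3 at 478 ± 96.8 and 0.292 ± 0.505, SLITRK1 at 750 ± 107 and 2.69 ± 2.63, NKX2-1 at 381 ± 43.5 and 1.52 ± 1.8, and PNPLA4 at 222 ± 52.1 and 0 in every library. DMD was at 2216 ± 14.6 in S134A-GR and 38.5 ± 13.3 in WT-GR cells, ZNF300 at 386 ± 41.7 and 1.14 ± 1.97, SPP1 at 1521 ± 33.2 and 101 ± 4.72, and THSD7B at 198 ± 11.4 and 8.27 ± 9.07. GTPBP6 met the rule at 4.44, is uncertain as above, and lost its call in 5 of 24 alternatives. limma called 7931 genes, 3730 higher and 4201 lower in S134A-GR cells, of which 1521 differed at least 2-fold, and values did not overlap for 52.4% of genes, where chance gives 10%. The share of higher calls was 47%, as in edgeR with TMM, and 64.9% in edgeR with scaling by library size only, which moved the median of all genes to 0.115 on the log2 scale. Of the genes called in both treatments, 5862 of 5884 had the same sign, where independent lists would share 2009.9. These 2 comparisons have no library in common, but each gene's estimate of the spread is shared, so their calls are not independent.

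In Dex 14 lists were lower in S134A-GR cells by the limma camera test. With an estimated correlation it called 0 of 26 lists, with 8 at an unadjusted p under 0.05, while fry called 22. Cholesterol genes were lower in 16 of 20 cases (17 adjusted over the list alone), with limma camera adjusted p = 3.62e-07 (adjusted p = 0.0931 with an estimated correlation). ATF4 and unfolded protein response genes were lower in 19 of 24 cases (19 adjusted over the list alone), with ASNS at -0.95 and limma camera adjusted p = 9.48e-07 (adjusted p = 0.0545 with an estimated correlation). Luminal markers were lower in 12 of 15 cases and higher in 1 (12 and 1 adjusted over the list alone), with KRT19 at -2.13 and limma camera adjusted p = 0.000109 (adjusted p = 0.0555 with an estimated correlation). Of 27 glucocorticoid-induced genes 15 were lower and 3 higher (15 and 3 adjusted over the list alone), with TSC22D3 at -0.62, ERRFI1 at -0.86 and GLUL at -0.55, and limma camera adjusted p = 0.0096 (adjusted p = 0.124 with an estimated correlation). With scaling by library size only, 13 of these were lower and 7 higher. TSC22D3 and ERRFI1 were already lower in vehicle, by log2 differences of -0.55 and -1.3. The response of TSC22D3 was not shown to differ (difference -0.07, limma adjusted p = 0.65), and ERRFI1 rose more on the log2 scale in S134A-GR cells (1.24 against 0.8, limma adjusted p = 0.013), a call lost with the replicate block and without WT-GR vehicle replicate 2 (difference 0.41) or S134A-GR vehicle replicate 1 (0.42). GLUL was not shown to differ in vehicle (-0.03, limma adjusted p = 0.499) and rose less in S134A-GR cells (0.36 against 0.87).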

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

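The tests of alternate haplotype sequences, of the direction of the genotype difference, of the WT-GR Dex library left out of the calls and of 2-fold genotype differences were chosen only after related results had been seen; the other tests in this part were chosen before their own results were seen, though after other features of the libraries were known.

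The results that stand out are the Dex responses that differ between the genotypes by limma's test of the difference, 66 genes in all. Higher in S134A-GR cells were the log2 responses of TNS4 (difference 2.55), FAM65C (2.07), EDN2 (1.63), SLC2A14 (1.47), ALPP (1.41), SDPR (1.14), STON2 (1.02), GPR89A (0.94), CCDC138 (0.9), FGD4 (0.9), LOX (0.69) and ERRFI1 (0.43). Lower were those of GTF2IRD2B (-1.65), LDB3 (-1.44), S1PR3 (-1.18), NRG2 (-1.03), ATOH8 (-1.02), STOM (-1.01), GATSL3 (-0.96), INPP5J (-0.92), IL6R (-0.89), FBXO32 (-0.78), GLUL (-0.51) and FKBP5 (-0.38).

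For these 66 genes the tables argue against the technical explanations tried, each within the limits given here. Genotype labels were exchanged within treatments after each gene's mean genotype difference was removed. That step changes the fitted trend and gives 71 calls with the real labels in place of 66. Of 100 splits 1, the real one, gave as many calls, and the highest other gave 1. This argues against a chance division of these libraries. It cannot exclude chance between cultures, since the libraries of a group may be technical. The count was also 1604 without WT-GR Dex replicate 3. WT-GR Dex replicates 2 and 3 held few single-read genes. Even so, the 69 genes called without replicate 1 showed a median 0.99 of their difference with it as the only WT-GR Dex library (95% bootstrap interval over genes 0.93 to 1.11). Distorted values in replicates 2 and 3 would give about 0, and noise in the 9 shared libraries 0.67 if all libraries varied alike. The WT-GR Dex libraries varied most, and the interval leaves out the spread between libraries. Within these limits the share, which rests on 1 library, argues against those 2 libraries as the source. Of the 69, 53 are among the 66, whose own share of 1.08 decides nothing because replicate 1 helped to call them. Only 4.5% of the genes had a mean value under 50 in any group, which argues against a distortion near 0 on the log scale for the other genes. FAM65C, EDN2 and LDB3, with some of the larger differences, are the genes under 50, and for them it stays open. The biological explanation the design offers, that the phosphorylation site shapes the response of these genes, stays open as an untested hypothesis, as does any other difference between the lines.

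A small group of abundant genes had erratic values within groups, 39 of 11641 with a mean value of at least 200 and a residual SD above 1 on the log2 scale, among them RPS18 and, named after their values were seen, TAP2, HLA-E, KIFC1 and CUTA. AGR2 was also among them, with values near 0 in S134A-GR vehicle (15.08, 0 and 7.127), and it deviated most in replicate 2 of that group. Of the 37 with a position, 7 lay in the major histocompatibility complex region of chromosome 6, against 31 other abundant genes, an odds ratio of 82.8 (95% interval 28.6 to 214, two-sided Fisher's exact p = 2.86e-11). Reads lost to alternate haplotype sequences of the genome build may therefore account for part of this group, and no biological explanation was tested. The 2 shallowest libraries were the most deviating ones for 12.8% of the genes, which argues against depth.

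The total for genotype in vehicle, 8061 genes, hardly moved between normalizations (ratio of counts at most 1.01). Its make-up did move, from 3804 higher and 4257 lower in limma to 4849 and 3285 in edgeR with library size only. A steady total therefore cannot exclude the scaling for single genes. With library size only the share of higher calls was 12.4 percentage points above that of limma. It was 10.6 above edgeR with TMM and 13.4 above edgeR with DESeq2 size factors. The balance of higher and lower genes may therefore come from the scaling. The test fixed first had named size and direction together, and this shift passed its limit for counting normalization as a source. Of the 9908 genes called for the mean genotype effect over both treatments, 3330 were Dex-responsive against 3089.3 expected, a ratio of 1.08 (95% bootstrap interval 1.06 to 1.09, at most 1.53 possible). Most of the 9908 were thus not called for Dex. The ratio set beforehand for hormone-responsive genes as carriers lay close to that ceiling, so the ratio does not decide this explanation. For the 1355 genes 2-fold apart in vehicle the ratio of 1.33 (1.23 to 1.42, at most 5.14 possible) leaves a part open. There were 43 genes with a mean above 100 in WT-GR vehicle that were more than 20-fold lower in S134A-GR cells in both treatments, such as NUP210, AGR2, HCLS1 and NKX2-1, against 3 the other way, DMD, ZNF300 and MAFIP, the last named after its values were seen. The receptor mutation and another difference between the lines cannot be told apart here, because the labels name no separate lines within a genotype.

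For each comparison of 2 groups, 10 splits of the 6 libraries are too few for a share under 0.05, and in each 1 split, the real one, gave as many limma calls. For Dex in WT-GR cells the real split gave 4455 calls and the highest other 18. The highest other split gave 0 calls beside 2513 for Dex in S134A-GR cells, 8061 for genotype in vehicle and 7931 for genotype in Dex.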

How the results depend on the processing

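Library weights, the deposited names, the other pseudocount and leaving out WT-GR Dex replicates 2 and 3 together were chosen after seeing the data, as was limma as the main test. edgeR with TMM had been fixed before as the main test on raw counts, and its use on recovered reads was chosen after. The other alternatives were fixed before. Those among them run on recovered reads, such as DESeq2 and scaling by library size only, had been fixed for raw counts. The gene filter, a value of at least 10 in at least 3 libraries, took the place of edgeR's filterByExpr, which had been fixed. Total counts of called genes and lists and of genes changed alike in both genotypes stayed within 1.5 times the reported ones except where given, and PDK4 and NR3C1 kept direction and call except where named. Across the alternatives other than the deposited names, PDK4 ran on the log2 scale from 2.19 to 2.32 for Dex in WT-GR cells and from 2.12 to 2.25 in S134A-GR cells. Beside those of PDK4 and NR3C1, 198 gene results are named in the text. Of these, 177 kept call and direction in every alternative other than the deposited names. Over their 4726 recomputed values 130 lost the call, 2 gained it and 0 past the threshold changed direction. Of the 130 losses, 119 fell on the 25 results for the difference of responses, so the pooled share does not describe those results. Below the threshold, GLUL between genotypes in vehicle was 0.04 with library size only.

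Counts of limma calls moved as follows, and the cause was not tested unless given. Fitting only the compared groups gave 2490 genes for Dex in WT-GR cells and 3439 in S134A-GR cells, which reverses their order in the main fit. Library weights, whose estimate stopped before it converged, gave 7113 in WT-GR cells, 5116 in S134A-GR cells, 2854 for the difference of responses and an overlap of 3146 genes. DESeq2 gave 504 genes for the difference of responses. Without WT-GR Dex replicates 2 and 3 that count was 2550, the ratio of median responses 0.48, and NR3C1 between genotypes in Dex was -0.25 and no longer past the threshold; the single WT-GR Dex library left is then assumed to vary like the other groups. Requiring a 2-fold change, which by construction lowers counts, gave 583 and 413 genes for Dex in WT-GR and S134A-GR cells, 13 for the difference of responses, 1355 and 1521 for genotype in vehicle and Dex, and an overlap of 287.

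Smaller counts moved too, here without the deposited names. The 8 genes with opposite responses became 4 with only the compared groups fitted, 18 with DESeq2, 71 without WT-GR Dex replicates 2 and 3 and 135 with library weights, and from 5 to 42 leaving out each library in turn. Of genes past a 2-fold change, the 13 for the difference of responses became 7 with the replicate block, 24 with DESeq2, 157 without WT-GR Dex replicates 2 and 3 and 275 with library weights, and from 6 to 75 leaving out each library in turn. The 583 for Dex in WT-GR cells became 945 with library weights and 328 with the stricter filter, which removes genes with low values, and the 1355 and 1521 for genotype became 755 and 753 with that filter.

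Leaving out each library in turn, the count for Dex in WT-GR cells ran from 2963 to 6094 and that for the difference of responses from 26 to 1604, the extremes being without WT-GR vehicle replicate 2 and without WT-GR Dex replicate 3 for both, with S134A-GR vehicle replicate 1 also giving 26. The second count also moved by over 1.5 times without WT-GR vehicle replicate 1 (37) and without any other S134A-GR library (30 to 33).

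With the Dex names as deposited, most genes are paired with the values of another gene, which is the cause of these changes: 13578 and 13549 calls for Dex, 4718 for the difference of responses, 4264 and 3995 for genotype in vehicle and Dex, and an overlap of 13020. PDK4 then turned to -9.1 and -7.89 for Dex in WT-GR and S134A-GR cells and to 0.58 between genotypes in Dex, and stayed at -0.64 in vehicle without passing. NR3C1 was -7.5 for Dex in S134A-GR cells, past the threshold, 0.18 between genotypes in Dex, and -0.41 in vehicle without passing.

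NR3C1 for Dex in S134A-GR cells passed the threshold at -0.18 with only the compared groups fitted and at -0.21 with library weights, and its difference between genotypes in Dex was -0.15 and did not pass with library size only; the causes were not tested. Of the lists, camera with an estimated correlation called 2 for Dex in WT-GR cells, 3 in S134A-GR cells, and 0 for the difference of responses, for genotype in vehicle and for genotype in Dex (0, 4 and 8 at an unadjusted p under 0.05). fry, which does not compare a list with other genes, called 20, 18, 0 (3 unadjusted), 22 and 22 lists in the same order.

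Libraries that share a replicate number did not vary together (r = -0.085 to 0.055 between their deviations from group means), and 1 of 12 libraries correlated best with its own number, so the numbers were not taken as pairs. With the number as a replicate block, limma called 25 genes for the difference of responses and 5 lists for Dex in WT-GR cells, where NF-kB genes were at adjusted p = 0.0514; the total counts of the other comparisons stayed within 1.5 times.

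What depth limits was not tested. On reads simulated at the recovered depths, limma found 36% of the smallest changes tried for Dex in WT-GR cells and 8% for the difference of responses. Between replicates of a group the chi-square statistic over its degrees of freedom was 7.65 to 46.21. It is a ratio of variances on recovered reads, which counting both mates of a pair would itself raise.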

Other observations

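Single genes of fuel use other than PDK4 moved with Dex, although their lists did not pass as a whole in WT-GR cells (next paragraph). CPT1A, the gate of mitochondrial fatty acid uptake, rose by 0.48 in WT-GR and 0.53 in S134A-GR cells, and the mitochondrial coactivator PPARGC1A by 1.51 and 1.4 on the log2 scale (limma adjusted p = 3.28e-06, 1.12e-06, 1.8e-06 and 3.58e-06). PDP1, the phosphatase that reactivates pyruvate dehydrogenase, fell by 0.52 and 0.55, and the kinase PDK1 fell by 0.3 and 0.35 (limma adjusted p = 4.8e-05, 2.87e-05, 0.00285 and 0.000994). The pyruvate dehydrogenase subunit PDHA1 rose by 0.16 in WT-GR cells (limma adjusted p = 0.00671), a call lost in 2 of 24 alternatives, and its change of 0.09 in S134A-GR cells did not pass (limma adjusted p = 0.119). DLAT, another subunit, was lower in S134A-GR cells, by -1.02 in vehicle and -0.85 in Dex (limma adjusted p = 2.69e-09 and 1.58e-08). In WT-GR cells Dex also raised MYC (0.8), the transition factor SNAI2 (0.92) and LOX (0.92), while HBEGF, JUN and VEGFA fell by 1.47, 1.2 and 1.02.

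The lists not yet given for Dex in WT-GR cells are listed here with adjusted p-values of limma's camera, and none of these passed. Of 24 ATF4 and unfolded protein response genes 4 rose and 5 fell (adjusted p = 0.845, with a median of 0.01, a mean of -0.04 and a downward test), and of 15 luminal markers 3 rose and 4 fell (adjusted p = 0.641). Further, 2 of 14 pyruvate dehydrogenase genes rose and 3 fell (adjusted p = 0.719, with a median of -0.06, a mean of 0.07 and a downward test), 3 of 17 TCA cycle genes rose (adjusted p = 0.207), 5 of 22 fatty acid oxidation genes rose (adjusted p = 0.153), 4 of 22 epithelial-mesenchymal transition genes rose and 6 fell (adjusted p = 0.936, with a median of -0.07, a mean of 0.08 and an upward test), and 8 of 31 migration genes rose and 6 fell (adjusted p = 0.845). In the same comparison, 10 of 26 TGF-beta targets rose and 6 fell (adjusted p = 0.158), 4 of 18 clock genes rose and 5 fell (adjusted p = 0.824, with a median of -0.09, a mean of 0.13 and a downward test), 1 of 22 mitosis genes rose and 6 fell (adjusted p = 0.153), 2 of 20 nuclear receptor cofactors rose and 5 fell (adjusted p = 0.936, with a median of 0, a mean of 0.18 and a downward test), 3 of 7 basal markers rose and 1 fell (adjusted p = 0.719, with a median of -0.27, a mean of 0.63 and an upward test), 1 of 10 histone genes rose (adjusted p = 0.648), and 4 of 15 housekeeping genes rose and 2 fell (adjusted p = 0.295). Of 5 blood cell markers limma, edgeR and DESeq2 each called 0, and 0 had an unadjusted p under 0.05 (adjusted p = 0.719). Adjusted over the list alone, the TCA cycle had 2 higher, the transition genes 6 higher and 6 lower, migration 10 and 8, TGF-beta 10 and 7, the clock 4 and 6, and the cofactors 3 and 5; the histones had 0 called by limma, with 2 at an unadjusted p under 0.05 and 1 each by edgeR and DESeq2 over all genes, and the other lists kept their counts.

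Scaling by library size only in edgeR moved the balance of several lists for Dex in WT-GR cells. Of pyruvate dehydrogenase genes 1 then rose and 6 fell (2 and 3 in edgeR with TMM), of migration genes 6 rose and 8 fell (9 and 6 with TMM), of TCA cycle genes 1 rose and 1 fell (3 rose with TMM), of housekeeping genes 2 rose and 3 fell (4 and 2 with TMM), and of transition genes 4 rose and 8 fell (6 and 4 with TMM), so the direction of these lists depended on the scaling. With library size only, 4 fatty acid oxidation genes rose and 1 fell, 8 TGF-beta targets rose and 7 fell, 6 p38 genes rose and 5 fell, and 3 basal markers rose and 1 fell. More genes fell than rose among glycolysis (7 and 3), immediate-early (10 and 4), clock (7 and 4), hypoxia (14 and 3), ATF4 and unfolded protein response (6 and 2), mitosis (9 and 1), cofactor (6 and 2) and luminal genes (4 and 2), and 8 cholesterol genes fell. Of the lists that passed, 16 interferon genes fell and 1 rose, 18 DNA replication genes fell, 10 growth arrest genes rose and 4 fell, and 13 NF-kB genes fell and 5 rose. In the other comparisons, the lists that passed for Dex in S134A-GR cells or for genotype kept the direction of their larger count.

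Further lists were lower in S134A-GR than in WT-GR cells in Dex, all by limma camera tests that were lost with an estimated correlation. They were glycolysis (15 of 23 lower and 2 higher, adjusted p = 0.000753, and adjusted p = 0.275 with an estimated correlation), hypoxia (13 of 20 lower and 4 higher, 0.00439 and 0.266), immediate-early genes (14 of 26 lower, 0.00496 and 0.266), fatty acid oxidation (12 of 22 lower and 1 higher, 0.0119 and 0.0931), NF-kB genes (13 of 25 lower and 5 higher, 0.0119 and 0.275), housekeeping genes (9 of 15 lower and 1 higher, 0.0158 and 0.275), TGF-beta targets (14 of 26 lower and 5 higher, 0.024 and 0.279), the p38 pathway (14 of 26 lower and 1 higher, 0.024 and 0.104), interferon genes (12 of 23 lower and 6 higher, 0.024 and 0.104) and the TCA cycle (8 of 17 lower and 2 higher, 0.0396 and 0.124). Adjusted over the list alone the lower counts were the same, the higher counts were 3 for glycolysis, 1 for immediate-early genes, 2 for housekeeping genes and 2 for the p38 pathway, and the others were the same. Examples are ACAT1 at -0.62, SDHD at -0.86 and BST2 at -4.51. With scaling by library size only, 7 of 15 housekeeping genes were lower and 2 higher, and their median was -0.01.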
